A study of Homo sapiens with 8 samples.

How the data were processed

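Raji cells, a Burkitt lymphoma B cell line, were compared as wild type and after CRISPR/Cas9 deletion of a super-enhancer on chromosome 1, called the RGS-SE knockout. The series places the super-enhancer between RGS1 and RGS13, while the interval in the sample labels, 192515157 to 192741754, contains both genes. RNA-seq and ATAC-seq, which counts transposase insertions into open chromatin, were each measured in 2 wild-type and 2 knockout samples, 8 libraries in all. Each ATAC library was made from 50000 cells. The series labels the replicates as biological and describes single knockout clones, without the number of clones, so genotype and clone cannot be separated.

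The authors' processing notes name Trim Galore, cutadapt, Trimmomatic, STAR, featureCounts, Bowtie2, HOMER and DESeq2 with the GRCh38 or hg38 genome. Their versions, order and settings, and the peak caller, are not given in the sources used here. Per the file headers, the authors' deposited tables hold DESeq2 results, with a row for each gene in the RNA table and for each peak in the ATAC table. In the authors' deposited tables, the signal of each gene or peak is the mean over the 4 libraries of counts divided by the authors' DESeq2 size factors. The authors give the log2 fold change and its standard error (SE) on the log2 scale. The Wald score in the authors' tables equals the fold change divided by its SE to within 8.17e-14 in the RNA table. The deposited p-value (p_value) of each gene or peak is that of a two-sided Wald test, and the adjusted p is its Benjamini-Hochberg value. The other unit in the deposited ATAC table is the distance of a peak to the nearest transcription start site in bp, beside HOMER's annotation of each peak.

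The tables hold no values per library. The quasi-likelihood test of edgeR, planned before the data were examined, could not be run without counts. The authors' DESeq2 Wald results were used in its place, with an adjusted p under 0.05 as the threshold. The tables do not name the direction of the fold change. A positive value was taken as higher in the knockout, because 1 peak in the targeted interval was close to absent on one side, which was taken as the knockout. This rests on that peak and on the noncoding RNA that starts there, since the other peaks of the labelled interval kept 97.2% of their summed fitted count. If the sign were coded the other way, every direction reported would turn.

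CPM values are the mean normalised count scaled to the table's summed mean normalised count. Fitted normalised counts per genotype were computed from the mean and the fold change, which takes both genotypes as 2 of the 4 libraries. The fitted fold change of a gene or peak with almost no reads in one genotype depends on the fit and is not a bound. RNA size factors were recovered from genes whose mean equals 1 read in 1 library divided by 4 times its size factor. All of the 3772 genes with a mean under 0.75 were sums of such steps within 1e-06. The depth of each ATAC library is unknown.

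Gene positions came from GENCODE release 44 on GRCh38. All 25377 gene identifiers were found there, and all 70312 peaks lay within hg38 chromosomes. The RNA table holds 22 repeated entries for genes of the pseudoautosomal regions, which were left out of comparisons across genes or positions.

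Gene lists, 24 in all, were fixed before the data were examined. They were the RGS genes, chemoattractant receptors and G protein signalling, adhesion and motility, germinal centre B cell genes, plasma cell genes, B cell receptor signalling, NF-kB, CD40 and LMP1 target genes, MYC targets and ribosome biogenesis, MHC class II, MHC class I, type I interferon response, BCL2 family and apoptosis, p53 targets, proliferation, immediate early genes, glycolysis and hypoxia, unfolded protein and integrated stress response, cholesterol synthesis, Polycomb, chromatin and DNA methylation regulators, markers of T and NK cells, of myeloid cells, and of epithelial, fibroblast and erythroid cells, mitochondrially encoded mRNAs and replication-dependent histone genes. Lists with at least 5 tested members were tested with cameraPR (limma 3.58.1 in R 4.3.3) on the Wald statistics, with a preset correlation between genes of 0.01, two-sided, Benjamini-Hochberg adjusted over the lists. A correlation estimated from the data could not be computed, because the tables hold no residuals.

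Named genes followed a rule set before the data were examined. They were the measured genes in the interval or within 1 Mb, the 10 largest increases and 10 largest decreases among protein-coding genes past the threshold with at least 1 CPM, and up to 4 members of each list with the smallest adjusted p (up to 2 where none passed). Named peaks were those in the interval, the 6 largest increases and 6 largest decreases with a mean at or above the median peak, and changed promoter peaks of named genes. The rule's requirement of no overlap between the genotypes' libraries could not be applied. Other genes named were chosen after their values were seen.

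Promoter and gene changes were compared with Fisher's exact test, two-sided, in Python 3.11.15 with scipy 1.17.1, taking the promoter peak with the highest mean for each gene. Median log2 fold changes per chromosome were compared over 23 chromosomes by a two-sided permutation test with 100000 resamples. The steps in this paragraph from here on were chosen after the data were seen. Medians were computed in windows of 5 Mb with at least 15 peaks or 3 genes whose mean was at least 100. A shifted region was a run of at least 3 windows with an absolute ATAC median of at least 0.3. The RNA windows were rotated along the genome against the ATAC windows to test their correlation. Motifs, 10 in all, were searched in hg38 under distal peaks with a mean of at least 50, and compared with unchanged distal peaks by Mantel-Haenszel odds ratios over 5 GC and 5 width strata. Biological process terms with 15 to 500 members, as the deposited RNA table assigns them, were tested with Fisher's exact test.

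Alternatives were an adjustment without the filter on low means, a minimum mean of 100, removal of interval peaks or shifted regions, and centring on chromosome medians or on the local ATAC median of the 5 Mb window. Others were removal of the trend on GC content in 20 bins, a Wald test against a 1.5-fold change, Wald statistics scaled by their interquartile range, a list correlation of 0.05 and ranked list statistics. The code was tested on data simulated from the reported SEs, which tests the code and not the SEs. The simulated changes were placed only in genes and peaks with a mean of at least 100, so recovery at lower means was not tested. They covered 200 of 16970 genes and 200 of 70159 peaks, while 19.2% of genes and 35.9% of peaks passed in the data. With so few changes the adjusted threshold was stricter, so the recovered shares are not the sensitivity of the reported calls. Of 50 genes each, 22% were recovered at 1.5-fold, 80% at 2-fold and 100% at 4-fold. Of 50 peaks each, 50% were recovered at 1.5-fold, 90% at 2-fold and 100% at 4-fold. The false share of calls was 2.58% for genes and 2.30% for peaks. Calculations used numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots matplotlib 3.10.9.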

Results

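RNA-seq and ATAC-seq profiles were collected from Raji Burkitt lymphoma cells, wild type and with a super-enhancer near the RGS genes knocked out, in 2 libraries per genotype and assay. RGS genes encode regulators of G protein signalling, which switch off signals from chemokine and other receptors in B cells. The series asks what a silencer-like noncoding RNA made from the super-enhancer does in B cell lymphoma. The RNA table covered 25377 genes with a summed mean normalised count of 3.28e+07. The ATAC table covered 70312 peaks of median width 757 bp with 1.99e+07. The RNA size factors were 1.30 and 0.717 in the wild-type libraries and 1.07 and 1.03 in the knockout libraries, so the wild-type pair differed 1.82-fold in relative depth and the knockout pair 1.03-fold. The most abundant gene, EEF1A1, which encodes a translation elongation factor, took 2.00% of the RNA counts, and the top 10 genes took 7.98%. Values per library were not analysed here, so spread between replicates enters only through the SE of each deposited fold change, with 2 libraries against 2. Its median was 0.214 for genes and 0.161 for peaks with a mean normalised count of at least 100, against 1.28 and 0.363 below that mean.

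The first comparison asked what changed at the targeted interval, chromosome 1 from 192515157 to 192741754 (hg38), and in genes near it. RGS1, which dampens chemokine receptor signalling in B cells and lies inside the interval at 192575763 to 192580024, rose by 3.49 log2 units (SE 0.18, DESeq2 Wald test adjusted p 7.54e-79), or 11.2-fold, in the authors' deposited table. RGS13, a related germinal centre regulator at 192636138 to 192660311, had a log2 fold change of -0.20 (SE 0.22, adjusted p 0.628) in the authors' deposited table and did not pass the threshold. RGS2, the next family member at 192809039 to 192812275, had -0.75 (SE 0.43, adjusted p 0.233) in the authors' deposited table. The noncoding RNA ENSG00000289995, at 192609359 to 192634544, had -6.72 (SE 2.28, adjusted p 0.0211) in the authors' deposited table at 0.278 CPM, a call that ended under a test against a 1.5-fold change and under scaled statistics. Of 18 measured genes in the interval or within 1 Mb, 12 were tested and RGS1 and ENSG00000289995 were the 2 past the threshold. Among the others tested, GLRX2, a mitochondrial glutaredoxin, and RO60, an RNA-binding autoantigen, had log2 fold changes of 0.45 and 0.30 in the authors' deposited table, and UCHL5 and CDC73 had -0.17 and 0.20.

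Accessibility in the interval was lost at 1 site. The peak at 192609102 to 192609836, which covers the start of ENSG00000289995, lies 29078 bp past the end of RGS1 and 26302 bp before RGS13, and had a log2 fold change of -11.71 (SE 1.45, adjusted p 2.16e-14) in the authors' deposited table. Its fitted normalised count was 622 in wild type and 0.186 in the knockout, and the next lowest value of any peak was -7.85. Per kb of peak, the fitted knockout count was 0.253, against a median of 11.9 and a 5th percentile of 4.24 among 191 other peaks that fell by at least 3 log2 units. The lowest of those peaks had 0.365. Choice of the peak with the lowest fold change favours a low count. The interval held 18 peaks, of which 3 were higher, 3 lower and 12 not past the threshold. Apart from the lost peak, their log2 fold changes lay between -0.97 and 1.14, and their summed fitted count in the knockout was 97.2% of wild type. The peaks at the promoters of RGS1 and RGS13 had log2 fold changes of -0.14 (adjusted p 0.381) and -0.04 (adjusted p 0.888) by the DESeq2 Wald test in the authors' deposited table. The nearest peaks on either side of the lost one left a span of 9337 bp, from 192605672 to 192615010, against a labelled interval of 226.598 kb, so loss of the whole labelled interval was not seen. Within 1 Mb outside the interval, 3 of 39 peaks were higher and 13 lower, with a median of -0.24.

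**Figure D1:**
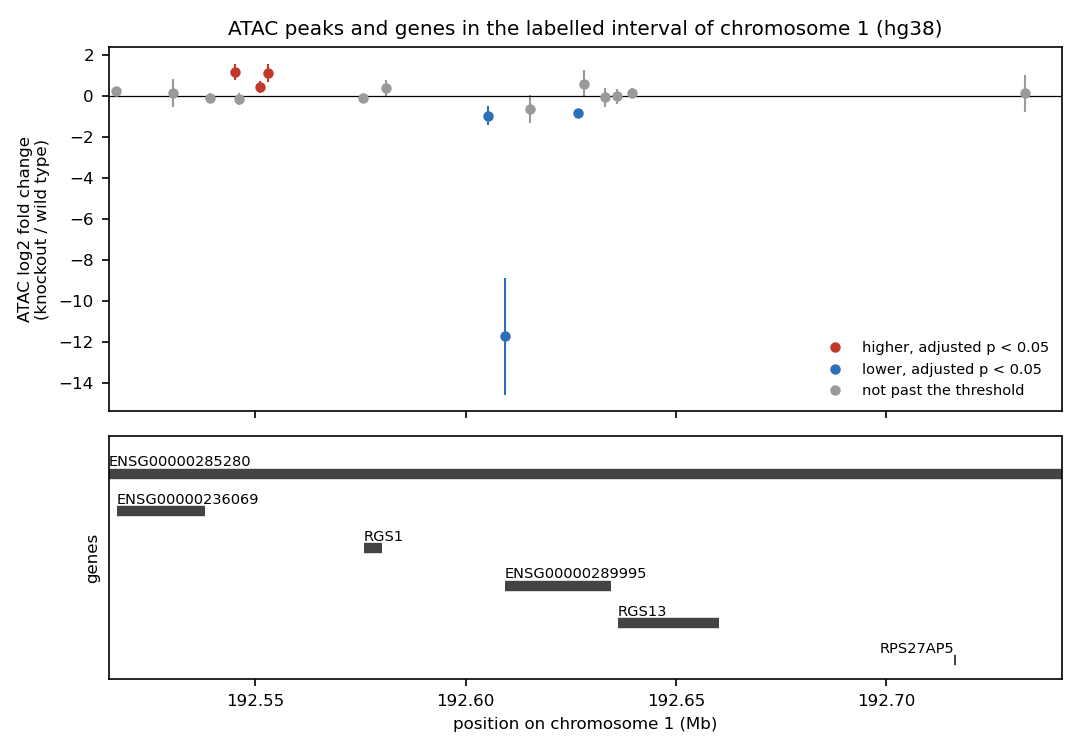
Log2 fold change (knockout over wild type) of the 18 ATAC peaks in the labelled interval of chromosome 1 against position in Mb, with bars for the 95% interval from the SE, and the 6 genes that overlap it. The peak at 192609102 lies at -11.71 and the others between -0.97 and 1.14.

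The second comparison asked which genes changed with the knockout. Among members of the fixed gene lists, IRF4, a transcription factor of activated B cells and plasma cells on chromosome 6 at 391739 to 411443, rose by 3.65 log2 units (SE 0.16, DESeq2 Wald test adjusted p 1.25e-112) in the authors' deposited table. The chemokine gene CCL22 rose by 3.24, CCR7, which guides cells to lymph nodes, by 2.92, and GPR183, an oxysterol receptor that positions B cells in follicles, by 3.22 in the authors' deposited table. Other genes went from almost no reads to clear expression or the reverse. GJC1, a gap junction protein gene, rose by 12.34 (SE 1.47), SCML2, a Polycomb group gene, by 11.47, and EIF4EBP1, a brake on translation, by 11.01 in the authors' deposited table. The other increases among the 10 largest were PUDP at 10.72, CPPED1 at 10.30, ZNF619 at 10.30, ZNF597 at 10.05, CHML at 10.04, RAB20 at 9.59 and CCDC181 at 9.08. Among decreases, MYEF2, a repressor of myelin genes, had -12.46 (SE 1.47), CCDC91, a Golgi transport gene, -10.92, and NAXD, a metabolite repair enzyme gene, -10.90 in the authors' deposited table. GLUL, which encodes glutamine synthetase, had the lowest value of these, from a fitted 1265 normalised counts to 0.175. The remaining decreases were TMLHE at -10.71, TRIB3 at -10.62, YIPF6 at -10.57, L3MBTL1 at -10.52, TMEM168 at -10.22 and ANKRD50 at -9.73. These fitted values for genes near 0 in one genotype are not bounds.

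In all, 3261 of 17013 tested genes, or 19.2%, were past the DESeq2 Wald threshold in the authors' deposited table, 1682 higher and 1579 lower in the knockout. Of these, 840 rose and 694 fell by at least 1 log2 unit. The other 8364 genes had a mean normalised count of at most 4.30 and no adjusted p. A test against a 1.5-fold change left 786 genes and scaled statistics left 665, both chosen after the data were seen.

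The gene lists asked which programmes of B cells moved. Targets of NF-kB, CD40 and the viral protein LMP1 rose with a median of 1.19, with the smallest adjusted p for CCL22, TNFAIP3, which feeds back on NF-kB, FCER2, the low-affinity IgE receptor gene, and TRAF1, a signalling adaptor, at 3.24, 2.86, 2.90 and 1.59 in the authors' deposited table. Of 28 tested members 18 were higher and 0 lower over all genes, and 21 and 0 adjusted over the list alone (cameraPR adjusted p 1.90e-25). Plasma cell genes rose with a median of 1.11, among them IRF4, PRDM1, which drives plasma cell fate, SLAMF7, a surface receptor, and HSP90B1, a chaperone, at 3.65, 2.29, 2.19 and 1.34 in the authors' deposited table. Of 15 tested, 10 were higher and 0 lower over all genes, and 14 and 0 adjusted over the list alone (adjusted p 3.94e-20 by cameraPR). MHC class II genes rose with a median of 1.39, with CIITA, their master regulator, at 1.39 (0.43 after centring on its local ATAC median), HLA-DRA at 1.57, HLA-DPB1 at 1.55 and HLA-DPA1 at 1.40 in the authors' deposited table. Of 15 tested, 14 were higher and 0 lower over all genes, with the same counts adjusted over the list alone (cameraPR adjusted p 4.24e-20). Germinal centre genes fell, with MME, which encodes CD10, at -1.12, CD27, a costimulatory receptor, at -1.07 and STAP1, a B cell receptor adaptor, at -0.93 in the authors' deposited table. Their median was -0.42, and 1 of 21 was higher and 8 lower over all genes and adjusted over the list alone (cameraPR adjusted p 4.32e-04). The calls of CD27 and STAP1 ended under the 1.5-fold test.

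Cholesterol synthesis genes had a median of 0.65, with HMGCS1 and MSMO1, both enzymes of the pathway, at 1.22 and 1.42 in the authors' deposited table. Of 21 tested, 11 were higher and 1 lower over all genes and adjusted over the list alone (cameraPR adjusted p 8.92e-06). Glycolysis and hypoxia genes had 4 of 20 higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone, with ALDOC, an aldolase gene, at 1.28 and BNIP3L, a mitophagy receptor gene, at 1.16 (0.46 after centring on its local ATAC median) in the authors' deposited table (cameraPR adjusted p 0.0105). The p53 targets had 6 of 18 higher and 0 lower over all genes, and 6 and 1 adjusted over the list alone, with TP53INP1, an autophagy and cell death gene, at 3.09 in the authors' deposited table (cameraPR adjusted p 0.0332). MHC class I genes had 7 of 15 higher and 3 lower over all genes and adjusted over the list alone (cameraPR adjusted p 0.0332), with HLA-B at 1.30 and PSMB8, an immunoproteasome subunit gene, at -1.21 in the authors' deposited table. Replication-dependent histone genes, whose mRNAs lack the poly(A) tail that the libraries selected, had 0 of 21 higher and 7 lower over all genes, and 0 and 8 adjusted over the list alone, with H1-3 at -8.59 in the authors' deposited table (cameraPR adjusted p 0.00487). Of the 9 lists past the threshold, 6 also passed at a preset correlation of 0.05, where glycolysis, p53 targets and MHC class I did not. The p53 list did not pass under ranks or either centring, the MHC class I list under ranks or chromosome centring, and the histone list after removal of the GC trend.

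The lists not past the threshold still held changed members. Among RGS genes, RGS1 rose and 6 of 13 fell over all genes and adjusted over the list alone, with RGS14, RGS16 and RGS3 at -1.24, -0.74 and -0.76 in the authors' deposited table (cameraPR adjusted p 0.680). These 3 calls ended under the 1.5-fold test and scaled statistics, and that of RGS3 also after removal of the GC trend. With ranked statistics the RGS list had a downward direction and a cameraPR adjusted p of 0.0505, still not past the threshold. Of the chemoattractant list 3 of 18 were higher and 5 lower over all genes, and 4 and 6 adjusted over the list alone (cameraPR adjusted p 0.743), and its median of -0.17 and the test's upward direction differed in sign. Adhesion genes had 6 of 17 higher and 3 lower, and 6 and 4 adjusted over the list alone (0.348), with VIM, an intermediate filament gene, at 1.87 and CD99, an adhesion glycoprotein gene, at -1.89 in the authors' deposited table. B cell receptor genes had 5 of 24 higher and 7 lower, and 6 and 8 adjusted over the list alone (0.348), with FCGR2B, an inhibitory Fc receptor gene, at -1.67 and PRKCB, a kinase gene of the pathway, at 1.47 (0.57 after centring on its local ATAC median) in the authors' deposited table. BCL2 family genes had 6 of 23 higher and 2 lower, and 6 and 3 adjusted over the list alone (0.130), with BCL2, a survival gene, at 1.52 in the authors' deposited table. Immediate early genes had 2 of 24 higher and 6 lower over all genes and adjusted over the list alone (0.368), with CCND1, a cyclin gene, at -6.82, and the MYC target list had 6 of 30 higher and 4 lower in both counts (0.620), with CCND2, another cyclin gene, at 7.21 in the authors' deposited table.

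Cell division genes did not pass the threshold as a group. Proliferation genes had 3 of 26 higher and 7 lower over all genes, and 3 and 8 adjusted over the list alone (0.396), with BUB1, a spindle checkpoint kinase gene, at 1.05 and MCM4, a replication helicase gene, at -0.80 in the authors' deposited table, a call that ended under local centring and the 1.5-fold test. Interferon response genes had 4 of 22 higher and 4 lower, and 4 and 5 adjusted over the list alone (0.619), with EIF2AK2, a sensor of double-stranded RNA, at -1.01 in the authors' deposited table, a call that ended under the 1.5-fold test and scaled statistics. Unfolded protein genes had 7 of 22 higher and 5 lower, and 8 and 5 adjusted over the list alone (0.508), with SESN2, a stress response gene, at 1.14 in the authors' deposited table. Their median of -0.03 and the test's upward direction differed in sign. Polycomb and chromatin genes had 4 of 23 higher and 5 lower, and 5 and 5 adjusted over the list alone (0.920), with RNF2, a ubiquitin ligase gene of Polycomb, at 1.97 in the authors' deposited table. Myeloid markers had 0 of 5 higher and 1 lower over all genes and adjusted over the list alone (0.680), where SPI1, which B cells also express, had -1.32 in the authors' deposited table, a call that ended with scaled statistics. T and NK cell markers, with 4 tested members of which 2 were lower, and epithelial, fibroblast and erythroid markers, with 3 tested members of which 1 was higher, were too few to test, and their most abundant members reached 4.71 and 12.7 CPM. Mitochondrially encoded mRNAs had 0 members in the RNA table.

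**Figure D2:**
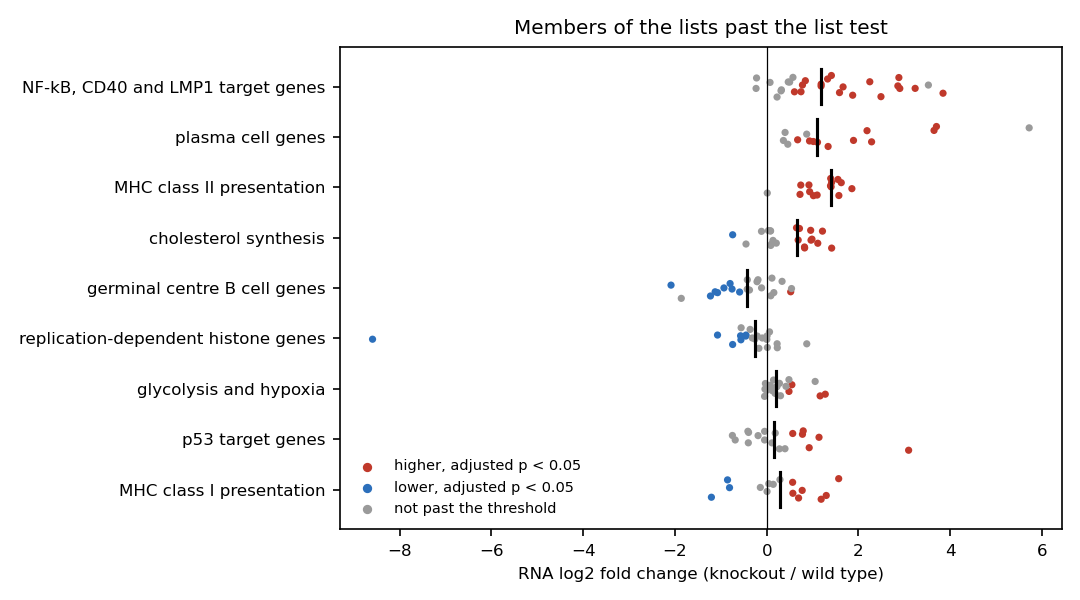
Log2 fold changes (knockout over wild type) of the tested members of the 9 gene lists past the threshold, with the median of each list as a line. The NF-kB, plasma cell and MHC class II lists had medians of 1.19, 1.11 and 1.39, and the germinal centre list -0.42.

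The third comparison asked where chromatin accessibility changed. At promoters, the peak of GLUL on chromosome 1 at 182391102 to 182392016 had -5.82 (SE 0.39, DESeq2 Wald test adjusted p 2.54e-47) and that of L3MBTL1, a chromatin reader gene, -5.71 (SE 0.20, adjusted p 8.50e-178) in the authors' deposited table. The promoter shared by ZNF597 and NAA60, on chromosome 16 at 3443249 to 3444385, rose by 6.93 in the authors' deposited table. A site annotated to the first intron of CPPED1, a phosphatase gene, at 12803113 to 12804124 rose by 7.81 there. That site also spans the boundary of the gene at 12803887, so it is not wholly intronic. The other large increases were 4 sites at STS, the steroid sulfatase gene on chromosome X, between 6.99 and 10.86, and not all of these calls were kept with scaled statistics. The other large decreases were NBPF8 at -7.62, LRRC37A6P at -6.23 and LINC00664 at -5.86 in the authors' deposited table, the first 2 in multicopy families where reads can be shared between copies. Among promoters of list members, those of IRF7, an interferon regulator, CCR7 and CIITA rose by 1.08, 0.78 and 0.84 in the authors' deposited table. However, the CIITA peak was at -0.12 after centring on its local median, and the CCR7 peak did not pass the 1.5-fold test or scaled statistics. The promoter of TRIB3, a stress kinase-like gene, fell by 4.72.

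Of 70312 peaks, 25228 or 35.9% were past the DESeq2 Wald threshold in the authors' deposited table, 14332 higher and 10896 lower in the knockout, and 7744 rose and 4072 fell by at least 1 log2 unit. Promoter peaks leaned to loss, with 1198 higher and 1681 lower of 8420, but among those changed by at least 1 log2 unit 324 were higher and 216 lower. Intergenic peaks leaned to gain, with 5925 higher and 3589 lower, as did introns with 6438 and 4878. The odds of a changed promoter peak being higher were 0.488 times those of a changed intron or intergenic peak (Fisher's exact test, two-sided, p 8.95e-72), a test chosen after the data were seen. Peaks of the same libraries are not independent replicates, so this p does not measure spread between libraries. The median mean was 706 for promoter, 86.1 for intergenic and 97.5 for intron peaks, so smaller changes could pass the threshold at promoters. In the main setting 56.8% of changed peaks were higher. A minimum mean of 100 gave 15146 changed peaks with 52.4% higher, of which 14880 were among the 25228. A test against a 1.5-fold change left 7039 with 70.5% higher, and scaled statistics 2189 with 67.0% higher.

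The fourth comparison asked whether expression and promoter accessibility moved together. GLUL, L3MBTL1, MYEF2, TRIB3, ANKRD50 and TMEM168, all nearly silent in the knockout, had promoter peaks at -5.82, -5.71, -4.73, -4.72, -4.88 and -2.93 in the authors' deposited table, of which that of ANKRD50 did not pass with scaled statistics. RAB20, a vesicle transport gene near 0 in wild type, had a promoter peak at 2.87. RGS1 is a counterexample, with expression up by 3.49 and a promoter peak at -0.14 in the authors' deposited table. Of 6776 genes with a promoter peak, 868 were past the threshold in both assays, with 382 higher in both, 386 lower in both, 69 higher in RNA and lower in ATAC, and 31 the reverse. The direction was shared by 88.5%, with an odds ratio of 68.9 (95% interval 44.1 to 108, Fisher's exact test, two-sided, p 1.31e-130). Across genes, which are not independent replicates, Spearman's rho was 0.366. With all assigned peaks the odds ratio was 14.0, and outside the shifted regions described with the chromosome windows it was 22.4.

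**Figure D3:**
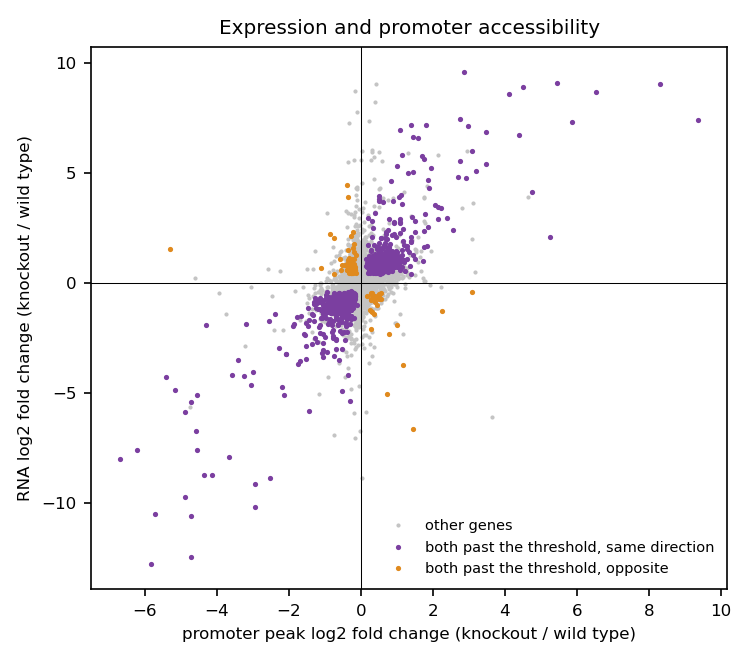
Log2 fold change of RNA against that of the promoter ATAC peak (knockout over wild type) for 6776 genes, with the 868 past the threshold in both assays in colour. Of these, 382 were higher and 386 lower in both assays.

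The fifth comparison asked whether whole chromosomes shifted in both assays, as a difference in copy number between clone and parent would make them do. Broad stretches rather than whole chromosomes shifted. Chromosome 16 from 0 to 25 Mb, which holds CIITA and CREBBP, had a median log2 fold change of 0.96 in ATAC and 0.81 in RNA. The short arm side of chromosome 8, from 0 to 45 Mb with EIF4EBP1, TNFRSF10B and FDFT1, had 0.75 and 0.78, and the same chromosome from 105 to 145 Mb, with BOP1, had -0.84 and -0.96. Chromosome 9 from 0 to 30 Mb, with DOCK8, had -1.04 and -0.81. Chromosome 6 from 70 to 120 Mb with PRDM1 and from 125 to 170 Mb with TNFAIP3 had ATAC medians of 0.54 and 0.53 and RNA medians of 0.73 and 0.67. The other regions were chromosome 2 from 210 to 245 Mb with NCL at 0.51 and 0.45, chromosome 8 from 50 to 70 Mb at 0.33 and 0.64, and chromosome 16 from 60 to 90 Mb at -0.57 and -0.71. Median changes per chromosome correlated between the assays over 23 chromosomes, with Pearson's r of 0.554 (permutation p 0.00429, adjusted over 2 relations 0.00858) and Spearman's rho of 0.304 (permutation p 0.158, adjusted 0.158). Without chromosomes 6 and 8, farthest from the ATAC median, r was 0.0764 (permutation p 0.743), so the relation rests on those chromosomes, and with a minimum mean of 100 the correlation of chromosome medians was 0.388 (permutation p 0.0652).

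The windows of 5 Mb were examined after these shifts were seen. Over 531 windows, medians correlated between the assays with Pearson's r of 0.669 and Spearman's rho of 0.363. The highest r of 530 rotations of one along the other was 0.500, a rotation p of 0.00188, the smallest they can give. The 9 regions, 6 higher and 3 lower over 320 Mb, had the same sign in both assays. In them 90.3% of genes with a mean of at least 100 had the sign of their region, against 50.6% outside with the sign of their window. They held 703 changed genes, 21.6% of all, of which 96.4% had the region's sign. In the regions 42.5% of tested genes were past the threshold, against 16.7% outside. CREBBP and DOCK8, at 0.66 and -1.01 in the authors' deposited table, had -0.33 and 0.0442 after centring on the local ATAC median. PRDM1, TNFAIP3 and CIITA expression stayed past the threshold under that centring, at 1.68, 2.28 and 0.43 in place of 2.29, 2.86 and 1.39. It subtracts the ATAC shift, which need not equal the RNA shift. The windows of PRDM1 and TNFAIP3 had RNA medians of 0.59 and 0.57 and ATAC medians of 0.60 and 0.58. CIITA's window had 1.07 in RNA and 0.96 in ATAC, so part of its 0.43 may be the RNA shift there. Whether CIITA rose beyond the RNA of its window was not tested. The expression calls of MCM4, FDFT1, NCL, BOP1, TNFRSF10B and KLF6, a transcription factor gene, and the promoter peak calls of PRDM1 at 2 sites, RGS3 and BNIP3L ended under local centring.

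**Figure D4:**
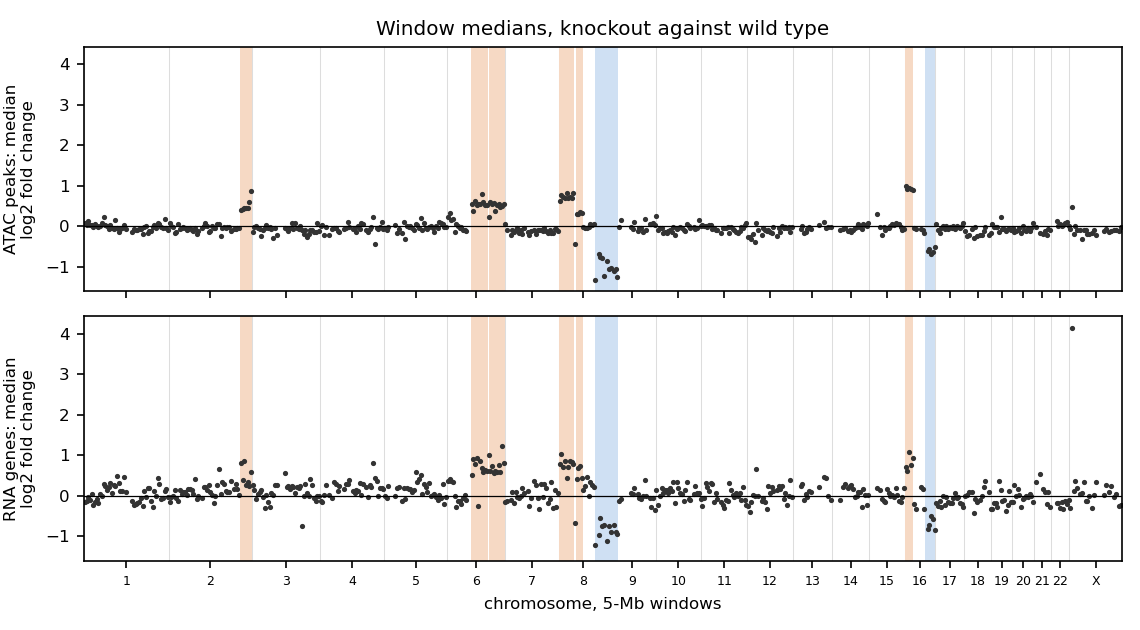
Median log2 fold change (knockout over wild type) of ATAC peaks and of RNA genes in 5 Mb windows along the 22 autosomes and X, with the 9 shifted regions shaded. Chromosome 16 from 0 to 25 Mb had medians of 0.96 in ATAC and 0.81 in RNA.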

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

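Except for adjustment without the filter, removal of interval peaks, all assigned peaks, omission of chromosome 1 and chromosome centring of the lists, the alternatives were tests chosen only after the results were seen. RGS1 and the lost interval peak kept direction and threshold under both centrings, the GC correction, the 1.5-fold test and scaled statistics, and the concordance odds ratio ranged from 14.0 to 112. The count of 3261 genes became 786 against 1.5-fold and 665 with scaled statistics, and that of 25228 peaks became 7039 and 2189, or 15146 with a minimum mean of 100, where fewer peaks were tested. The 1.5-fold test is stricter by construction, and scaling because the measured scale of the Wald statistics was 1.71 for genes and 2.51 for peaks. Adjustment without the filter changed no peak call, since every peak had an adjusted p. The other settings called 2420 to 3130 genes and 19752 to 25222 peaks, not all of them the same: the GC correction called 2805 genes, of which 2348 were among the 3261, and local centring 21522 peaks, of which 19459 were among the 25228. Of 148 named genes and peaks past the threshold, 95 kept their call with scaled statistics. Centring on the local ATAC median reversed CREBBP expression to -0.33 and DOCK8 to 0.0442. It also turned the promoter peaks of CREBBP to -0.30, CIITA to -0.12, NCL to -0.0544, FDFT1 to -0.00159 and DOCK8 to 0.0134. Each had the ATAC median of its window subtracted. The windows of CREBBP and DOCK8 had ATAC medians of 0.99 and -1.06 but RNA medians of 0.71 and -0.73. The reversed expression values therefore do not show these genes moving against the RNA of their region. MHC class I lost its call at a correlation of 0.05 (adjusted p 0.116), under ranks (0.152) and under chromosome centring (0.464). The p53 list lost its call under the same settings (0.119, 0.337 and 0.104) and under local centring (0.0687), glycolysis at a correlation of 0.05 (0.0677), and histone genes under the GC correction (0.0681), and the cause was not tested. The correlation of chromosome medians was 0.388 with a minimum mean of 100, the cause of which was not tested, and 0.0764 without chromosomes 6 and 8. No paired analysis was possible because the tables hold no values per library. For the same reason the following, planned before the data were examined, were not run: another count test, other size factors, total-count scaling, CPM filters, limma-voom, glmTreat, the replicate block, omission of each library, an estimated correlation and fry. Low-count genes had larger SEs, with a median of 1.28 under a mean of 100 and 0.214 from that mean up, and the part of depth in this was not tested.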

Other observations

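The Xp22.31 interval, and the tests of gene ontology terms, of genes near 0 in one genotype, of the copy-number, GC and few-genes readings of the regional shifts, and of motifs other than kB were chosen only after the results they concern were seen. The interferon-inducible chemokine genes CXCL9 and CXCL10 rose by 4.58 and 3.96 log2 units in the authors' deposited table, and CCL17 and CCL3, chemokine genes on the NF-kB list, by 3.84 and 2.88. The immunoglobulin constant genes IGHG2 and IGKC rose, IGHG2 by 5.34 at 2.08 CPM and IGKC by 1.02 at 556 CPM in the authors' deposited table, and reads of IGHG2 can be shared between IgG paralogs. These 6 genes were chosen after their values were seen. Of 662 annotated genes higher by at least 1 log2 unit, 33 belonged to the 180 immune response genes, against 10.2 by chance (Fisher's exact test, Benjamini-Hochberg adjusted p 2.14e-06 over 1225 terms). The 19 chemokine signalling genes included 7 of them (adjusted p 0.00784) and the 172 genes of G protein-coupled receptor signalling 25 (adjusted p 0.00241).

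Some genes, among them CHML of the G protein-coupled receptor term, switched between near absence and expression. In the knockout, 28 genes rose and 32 fell by over 8 log2 units in the authors' deposited table, among them GLUL, MYEF2 and TRIB3, which were lost, and GJC1, CHML and EIF4EBP1, which appeared. Of the 32 that fell, 11 had a promoter peak and all 11 peaks fell past the threshold, with a median of -4.72. Of the 28 that rose, 9 had one, of which 6 rose and 3 were not past the threshold, with a median of 4.13. Of the 28, 6 lay in the shifted regions, and of the 32, 1 did, against 1654 of all 17013 tested genes. Whether they mark differences between clones was not tested.

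The 9 shifted regions carried signs shared by chromatin and expression. A few strongly changed genes per region were argued against, since 90.3% of genes there had the sign of their region against 50.6% outside. GC bias as the whole cause was argued against by the RNA, where fold changes followed GC content (Spearman's rho -0.374) and 82.7% of the median absolute shift was left after the GC correction. In ATAC rho was 0.0119, so there was almost no rising or falling trend, although the medians of the GC bins spanned 0.168. After the GC correction 99.8% of the median absolute ATAC shift was left. A copy-number difference between the genotypes is a candidate explanation, and no DNA-based count was analysed here. The window correlation of 0.669 exceeded the 0.500 of the highest rotation, so shifts in both assays fell at the same positions. Any cause acting on a whole region would give that, so the rotations cannot single out copy number. A broad change of chromatin without a change in DNA was not tested.

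At Xp22.31, 12 of 12 peaks from 7059138 to 7264833 on chromosome X were higher by 6.99 to 10.86 log2 units, with STS at 9.04, chosen after its value was seen, and PUDP at 10.72 in the authors' deposited table. The flanking peaks were at 0.48 (DESeq2 Wald test adjusted p 0.212) and 0.97 (adjusted p 0.153) in the authors' deposited table. Closed chromatin on DNA that is present was argued against by a fitted wild-type median of 0.406 counts per kb of peak, below the 5th percentile of 3.10 and the median of 10.6 among 617 other peaks with at least 3 log2 units of gain. Selection of these peaks by their large gain favours a low count, although only 8 other peaks in the table had a lower fitted count per kb in either genotype. A deletion present in the wild-type cells sampled and not in the knockout clones may account for it, and no DNA-based test was made.

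The rise of NF-kB targets such as TNFAIP3, plasma cell genes such as PRDM1 and MHC class II genes such as CIITA was weighed against both technical readings. After subtraction of the local ATAC shift the largest cameraPR adjusted p of the 3 lists was 1.49e-19, and after removal of the GC trend 3.00e-22. This argues against GC bias, and against copy number at the members' own loci, as the whole cause. Only 1 of 28 tested NF-kB, 2 of 15 plasma cell and 1 of 15 MHC class II genes lay in shifted regions. The subtraction could therefore change little. It cannot address copy number of a regulator in those regions, such as CIITA, that acts on genes elsewhere. The kB motif was in 23.4% of 4482 gained distal peaks and 13.4% of 20261 unchanged ones, an odds ratio of 1.95 (95% interval 1.79 to 2.11), and its odds ratio in lost peaks was 0.655. Higher NF-kB activity in the knockout cells may underlie part of the gain, although peaks assigned to the NF-kB list's own genes shifted little in the median. Of 140 such peaks 34 were higher and 14 lower, with a median log2 fold change of 0.00149. The medians were 0.57 for peaks of plasma cell genes and 0.34 for those of MHC class II genes. The kB motif was also not the only motif to differ among 20 such tests. AP1, RUNX, OCT and E-box motifs were enriched in gained peaks too, at 1.40, 1.34, 1.18 and 1.19, and OCT motifs more so in lost peaks, at 1.39. CTCF motifs were depleted in gained and lost peaks, at 0.151 and 0.246, so the unchanged peaks also differed in kind. Whether the deletion or a difference between clones raised these genes was not tested.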
